A study of Homo sapiens with 12 samples.

How the data were processed

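The values were deposited by the authors as linear probe set intensities from 1-colour oligonucleotide arrays, with 54675 probe sets in each of 12 arrays. Per the labels' protocols, total RNA was extracted with a column kit and DNase, and 1 µg was amplified by in vitro transcription and labelled with biotin. How the probe signals were summarized and normalized is not given in the sources used here. The scanner's own files were not used here. The deposited intensities ran from 0.7 to 14510.65 on a similar scale in all arrays and were taken without further scaling.

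Intensities under 16 were set to 16 and log2 values were taken, so that 4 is the lowest log2 value. The platform's annotation, as given in the reference tables used here, named 1 gene for 41097 probe sets and several genes for 1801, and 11777 probe sets were not named here. Only probe sets with 1 gene were used. Each of 19775 genes was represented by the probe set with the highest mean over all arrays. The 4139 genes whose probe set lay in the lowest 30% of all probe sets by mean were left out, which left 15636 genes to test.

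Tests were made with limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The comparison after induction used all 12 arrays in a fit with 6 coefficients: the 4 times, the difference between constructs at 0 h, and a common difference at 24, 48 and 72 h. It had 6 residual degrees of freedom, and moderation added 1.39. The change beyond time 0 was the contrast of those 2 differences. The single times, the change of the effect from 24 to 72 h and the time course of scrambled cells came from a fit of 8 groups with 4 residual degrees of freedom (0.91 added). In that fit all spread came from the scrambled pairs. The design, the main tests, the 20 gene lists and most alternatives were fixed before the data were examined. The comparisons of scrambled cells at 24 and 48 h with 0 h, and the list tests other than those after induction, were added after the data were seen.

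The 20 lists were written from general knowledge of each process: NuRD subunits, genes linked to PAX3-FOXO1, myogenic regulators and early markers, sarcomere and muscle differentiation, cardiac muscle, G2 and mitosis, G1/S and replication, p53 targets, cell death, interferon response, amino acid and endoplasmic reticulum stress, cholesterol synthesis, neuronal genes, collagen and matrix, TGF-beta and YAP response, immediate early genes, cancer-testis genes, glycolysis and hypoxia, ribosome biogenesis with MYC-linked growth, and markers of blood, epithelial and endothelial cells. Some genes stand in more than one list. Lists were tested with limma camera at a preset correlation of 0.01 between genes, adjusted over the 20 lists, and again with the correlation estimated from the data. Members were counted by their adjusted p over all genes tested and by the p adjusted over the list alone.

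The genes named follow a fixed rule. CHD4 was named first. Next came the 12 highest and 12 lowest log2 fold changes among genes that passed after induction and lay beyond both scrambled arrays at each induced time. From each list up to 4 members with the smallest adjusted p were named, and for other comparisons the 5 highest and 5 lowest past the threshold. Genes outside this rule, such as CHD5 and members of lists that moved in scrambled cells, were chosen after their values were seen.

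Each gene comparison and the list tests after induction were recomputed with quantile normalization, with a common 75th percentile, without the filter, with the lowest 50% left out, with the mean of all probe sets of a gene, with a variance trend and robust moderation, with array weights and without each array in turn. List tests of the other comparisons were repeated only with an estimated correlation. The comparison after induction was also made with induced arrays only, with the 8 groups and without time, and counts also with a log2 fold change of at least 1. A pair of alternatives was added after the data were seen: an offset of 16 in place of the floor, and leaving out genes at the floor in one construct. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and pandas 2.3.3.

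The fits were tried on simulated values for 15636 genes, 200 of them changed, in 10 runs. After induction, 34.2%, 61.4%, 81% and 87% of genes with a true log2 change of 0.25, 0.5, 1 and 2 were recovered, and 6.79% of the calls were false. At 24 h these were 1.8%, 27.4%, 58.4% and 77.8%, with 8.52% false, and at 72 h 0.6%, 27.4%, 60.4% and 77.8%, with 8.38% false. With no genes changed, the comparison at 0 h gave 0.3 calls on average and that of 72 with 24 h gave 0. In 1 run a list lifted by 0.5 reached a limma camera adjusted p of 3.18e-72, and 0 other lists passed. The simulated genes varied independently, whereas the ribosome biogenesis list had an estimated correlation of 0.192 in the data. The run therefore cannot show how often the preset correlation passes lists falsely here.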

Results

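Gene expression was measured in Rh4 cells, an established line of alveolar rhabdomyosarcoma, a cancer of the muscle lineage usually driven by a fusion of PAX3 or PAX7 with FOXO1. The cells carried a doxycycline-inducible short hairpin RNA (shRNA) against CHD4, the ATPase of the NuRD chromatin remodelling complex, or a scrambled shRNA as control. Arrays covered 4 times: before doxycycline (0 h) and 24, 48 and 72 h after doxycycline was added at 100 ng/ml. Each time had 2 scrambled arrays and 1 CHD4 shRNA array, 12 arrays in 8 groups. The labels do not say whether the paired scrambled arrays came from separate cultures, so each p-value measures the spread between these arrays, which may be technical. The 12 arrays were alike in brightness, with median intensities from 26.33 to 29.16 and 75th percentiles from 275.6 to 306.2. Between 40.5% and 41.57% of the probe sets lay under the intensity floor of 16. The log2 difference within a scrambled pair had an SD of 0.2142 to 0.2419 over genes. The number of arrays limits the precision of every value below.

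The targeted gene was examined first, to see whether the hairpin lowered CHD4 in each array carrying it. All 3 CHD4 probe sets were lower in the CHD4 shRNA arrays at 24, 48 and 72 h than in both scrambled arrays of the same time, and none passed the threshold before induction. The brightest had intensities of 2173.6, 2165.1 and 2023.9 in the CHD4 shRNA arrays at 24, 48 and 72 h. The scrambled arrays read 3302.1 and 3285.9 at 24 h, 3339 and 3360 at 48 h, and 3312.8 and 3298.8 at 72 h. At 0 h the CHD4 shRNA array read 3433.9 and the scrambled arrays 3309.9 and 2993.2. After induction this probe set had a log2 fold change of −0.65 ± 0.04 (SE), or 63.9% of the scrambled level (limma adjusted p = 3.73e-05 over the genes tested). Its mean log2 intensity was 11.70 ± 0.01 (SD, n = 6) in scrambled and 11.05 ± 0.06 (SD, n = 3) in CHD4 shRNA arrays, with limma as the test. The 3 probe sets differed in the size of the fall. The second brightest stood at 26.8% of scrambled (log2 fold change −1.90 ± 0.15, limma adjusted p over probe sets = 0.000151), with intensities of 66.68, 49.2 and 72.08 at 24, 48 and 72 h against 198.79 to 261.5 in scrambled arrays with doxycycline. At 0 h it read 218.61 with the CHD4 hairpin and 241.63 and 178.41 without it. The dimmest was under the floor in all 3 induced CHD4 shRNA arrays, at 11.28, 14.37 and 9.01, against 32.13 to 42.42 in scrambled arrays with doxycycline. It was therefore at least 2.23-fold lower (limma adjusted p over probe sets = 0.000355). Before induction it read 28.29 in the CHD4 shRNA array and 40.83 and 29.17 in the scrambled arrays. The fold change of the brightest probe set before induction was 0.13 ± 0.07 (limma adjusted p = 0.731), and the change beyond it was −0.77 ± 0.08 (limma adjusted p = 0.00248).

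**Figure D1:**
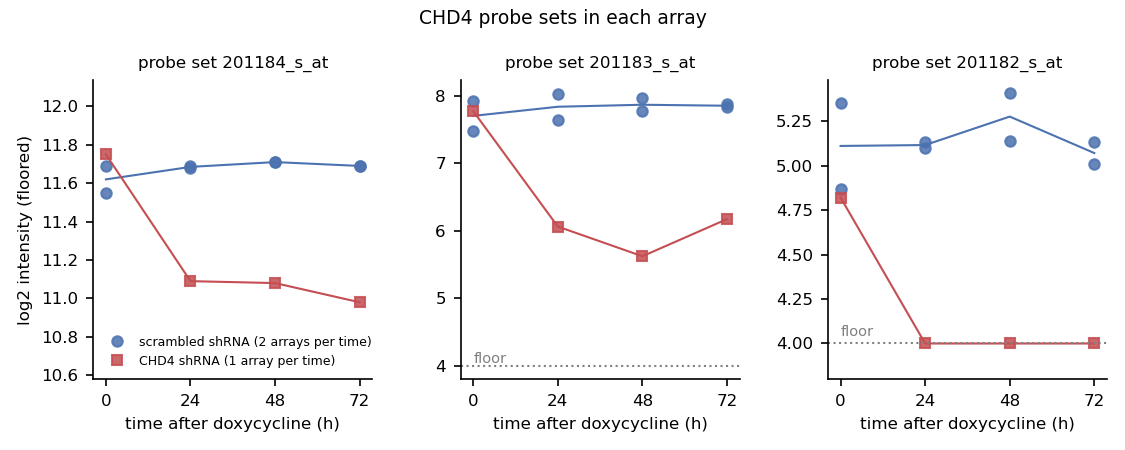
Log2 intensity (floored) of the 3 CHD4 probe sets against hours after doxycycline, with 1 point per array and lines through the group means; the dotted line marks the floor where it lies within a panel. The CHD4 shRNA arrays lie below both scrambled arrays at 24, 48 and 72 h, by a log2 fold change of −0.65 for the brightest and −1.90 for the second brightest.

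The main comparison asked which genes changed in Rh4 cells when CHD4 was silenced. RGS4, which speeds the turn-off of G protein signalling, rose by the largest factor, 61.4-fold, from a mean log2 intensity of 4.40 ± 0.28 (SD) in the 6 scrambled arrays to 10.34 ± 1.39 in the 3 CHD4 shRNA arrays (log2 fold change 5.94 ± 0.42 SE, limma adjusted p = 7.58e-05). The selenium transport protein gene SELENOP rose 13.6-fold (3.76 ± 0.59, limma adjusted p = 0.00184), the heavy neurofilament gene NEFH 12.2-fold (3.61 ± 0.36), the antiviral membrane protein gene IFITM1 11.1-fold (3.47 ± 0.42) and the sodium channel gene SCN9A 9.57-fold (3.26 ± 0.41). ISOC1, named for an isochorismatase domain, fell 6.60-fold (−2.72 ± 0.07, limma adjusted p = 3.62e-06), the calcium sensor gene NCALD 6-fold (−2.59 ± 0.26) and C1QBP, which encodes a mitochondrial matrix protein, 5.41-fold (−2.43 ± 0.08, limma adjusted p = 6.17e-06). MYC, the growth-promoting transcription factor, fell 3.84-fold (−1.94 ± 0.29, limma adjusted p = 0.00162).

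Among the other genes with the highest fold changes, the ubiquitin ligase family gene PDZRN4 rose 9.14-fold, the neutrophil chemokine gene CXCL8 8.72-fold, CDH5, which encodes the endothelial cadherin, 8.71-fold and SSX3, of a family normally expressed in testis, 7.69-fold. The pseudogene TPTE2P2, the guanylate cyclase gene GUCY2D and the transcription factor gene RFX4 were at the floor in all 6 scrambled arrays with doxycycline and stood at least 9.51-fold, 9.42-fold and 8.91-fold higher. On the lower side, the small GTPase gene RAB39B fell 5.32-fold, KANK4, of a family that regulates the cytoskeleton, 5.09-fold, SLC66A3 4.49-fold, the axonal transport adaptor gene FEZ1 4.41-fold, the WNT pathway gene DIXDC1 4.38-fold, the solute carrier gene SLC35F2 4.18-fold and SNAP91, active in clathrin coat assembly at synapses, 3.84-fold. The myelin gene MOBP fell at least 5.31-fold, with 2 of its 3 CHD4 shRNA arrays at the floor. Floored values make some other folds lower bounds in part: IFITM1 and PDZRN4 were at the floor in 3 of the 6 scrambled arrays with doxycycline, CXCL8 in 2, and RGS4, SCN9A and SSX3 in 1.

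In all, 4236 genes were higher and 2416 lower after induction, 6652 of 15636 tested or 42.5% (limma, Benjamini-Hochberg adjusted). Most shifts were small: the median absolute log2 fold change of these genes was 0.408, while 492 rose and 208 fell by at least 2-fold. Of all genes tested, 4669 lay above and 2667 below both scrambled arrays at every induced time. Were the arrays of a time interchangeable and the times independent, 3.70% of genes, or 579, would do so each way. Technical scrambled pairs, or any difference shared by the CHD4 shRNA arrays, would raise that number, so it is no measure of chance here. The split of higher against lower genes moved with the scaling: 63.7% were higher with the deposited values, 54.8% after quantile normalization (3608 higher, 2972 lower) and 49.6% with each array set to the same 75th percentile (3197 higher, 3251 lower). Each induced time had 1 CHD4 shRNA array, and the spread came from the scrambled pairs and from the CHD4 shRNA arrays around their mean effect.

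**Figure D2:**
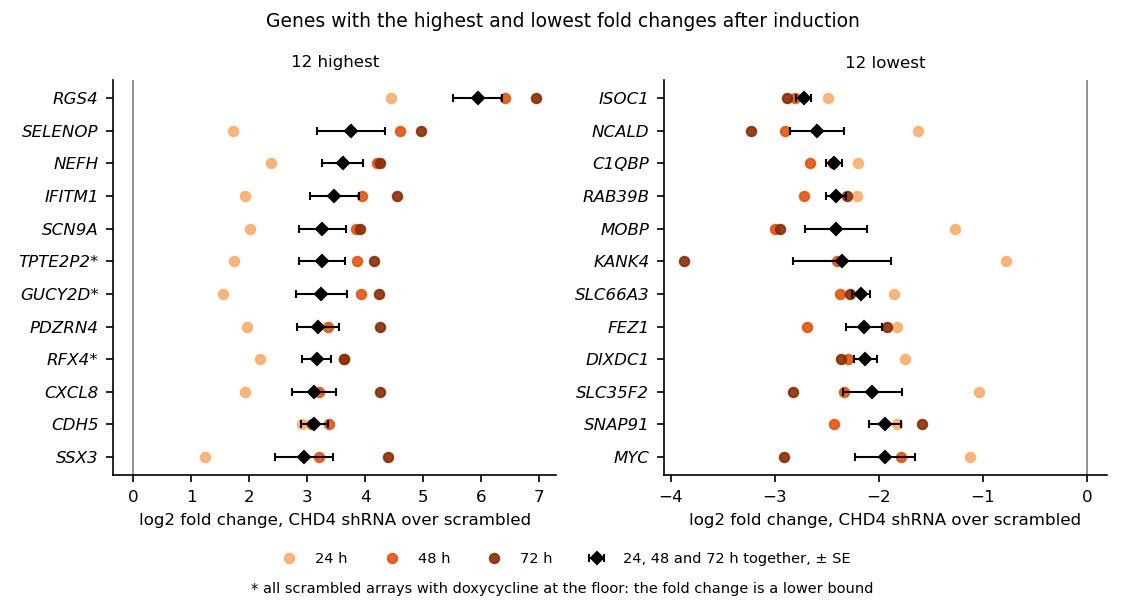
Log2 fold change of CHD4 shRNA over scrambled arrays (horizontal axis) for the 12 genes with the highest and the 12 with the lowest values after induction; diamonds with bars give the fit over 24, 48 and 72 h ± SE, and circles the value at each time. RGS4 lies farthest from 0 at 5.94, and ISOC1 is the lowest at −2.72.

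The balance of RNA ends differed between the constructs in the same arrays. The β-actin control probe sets, placed at the 3′ and 5′ ends of the transcript, gave a log2 difference of 2.235 to 2.536 in the 8 scrambled arrays and 2.291 in the CHD4 shRNA array at 0 h. It was 2.855, 3.655 and 3.971 in the CHD4 shRNA arrays at 24, 48 and 72 h. Relative to scrambled arrays of the same time this was a rise of 0.55, 1.18 and 1.44, against an SD of 0.06 within scrambled pairs. The 5′ signal of β-actin stood at −0.51, −1.17 and −1.40 relative to scrambled and the 3′ signal at 0.03, 0.01 and 0.04. The same difference for GAPDH was −0.01, 0.26 and 0.11, with a pair SD of 0.04. This shift accompanied the higher and lower genes above and every gene group below.

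**Figure D3:**
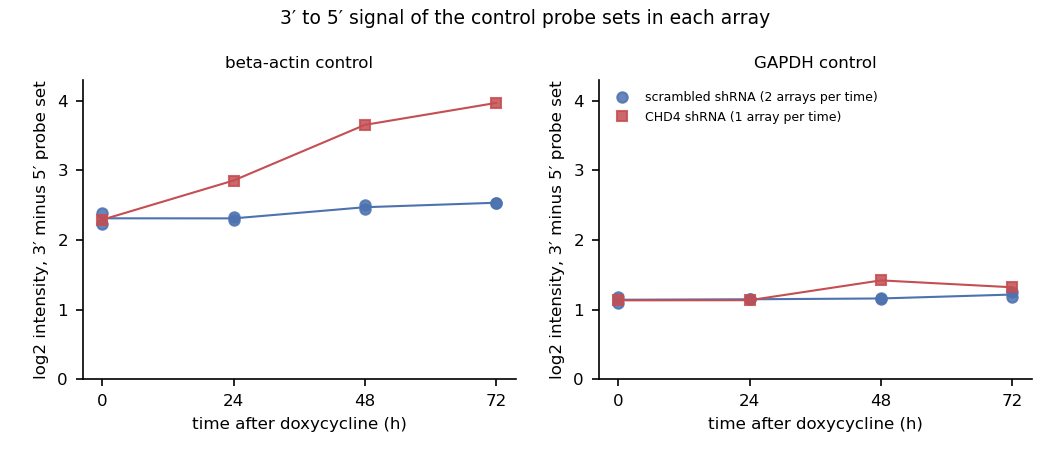
Log2 intensity of the 3′ minus the 5′ control probe set of β-actin and GAPDH in each array against hours after doxycycline, with lines through the group means. The β-actin difference in CHD4 shRNA arrays goes from 2.291 at 0 h to 3.971 at 72 h, while the scrambled arrays stay between 2.235 and 2.536.

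Groups of genes were then compared, to see which programmes of these cells moved. Genes of ribosome biogenesis and MYC-linked growth fell: 13 of 22 measured members were lower, none was higher and 9 did not pass (14 lower when adjusted over the list alone). Among them were PES1, needed for maturation of the large ribosomal subunit (−1.12 ± 0.04 SE), the spermidine synthase gene SRM (−0.66 ± 0.07), the rRNA methyltransferase gene NOP2 (−0.46 ± 0.03) and WDR43 (−0.18 ± 0.02). The list was lower than other genes by limma camera with a preset correlation (adjusted p = 2.96e-06; adjusted p = 0.457 with an estimated correlation). Targets of p53 rose: 13 of 21 were higher, 1 was lower and 7 did not pass, the same counts as adjusted over the list alone. The cell cycle inhibitor gene CDKN1A rose 2.14-fold (1.09 ± 0.06), SESN2 1.75-fold, TP53INP1 1.73-fold and the DNA repair gene DDB2 1.57-fold. The p53 list passed limma camera with the preset correlation (adjusted p = 0.025; adjusted p = 0.457 with an estimated correlation). Without the CHD4 shRNA array of 24 h this became an adjusted p of 0.0779, with the stricter filter on dim genes 0.0768 and with array weights 0.125.

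None of the other 18 lists passed limma camera with either correlation, so the counts below describe members, not a shift of the list. Rises and falls of members, here and below, are against scrambled arrays of the same times. Differences already present at 0 h were not removed from them. Counts adjusted over the list alone were the same as those over all genes tested unless a second count is given. Muscle genes went both ways. Of 27 sarcomere and differentiation genes, 6 were higher, 3 lower and 18 not past the threshold: the perinatal myosin gene MYH8 rose 3.79-fold, the myosin light chain gene MYL1 2.24-fold and CASQ2, for a calcium store protein, 1.57-fold, while the cardiac actin gene ACTC1 fell 1.24-fold (limma camera adjusted p = 0.897). The balance of that list turned to 5 higher and 6 lower with 75th percentile scaling. Of 18 myogenic regulators and early markers, 5 were higher and 4 lower, among them the integrin gene ITGA7 (1.05 ± 0.09) and MEF2A (0.22 ± 0.03) on the higher side and MEF2D (−1.04 ± 0.09) and EYA1 (−0.33 ± 0.05) on the lower (adjusted p = 0.831). They became 3 higher and 5 lower with 75th percentile scaling. Of 13 cardiac muscle genes, 3 were higher and 1 lower (1 and 1 when adjusted over the list alone; adjusted p = 0.935). The calcium pump regulator gene PLN rose 2.04-fold and TNNI3 1.87-fold, while GATA6 stood at −0.17 ± 0.05. TNNI3 was at the floor in 2 of the 12 arrays, so its fold is not exact. RYR2 also passed as higher, with all scrambled arrays and 1 of the 3 CHD4 shRNA arrays at the floor, so that the size of its change is not known. Among 31 genes linked to PAX3-FOXO1 in earlier work, 10 were higher and 8 lower, and 6 and 9 after quantile normalization or 75th percentile scaling (adjusted p = 0.935). The receptor genes PDGFRA (0.76 ± 0.06) and MET (0.32 ± 0.03), PODXL (0.49 ± 0.05) and NELL1 (0.36 ± 0.03) were higher. ALK (−1.75 ± 0.22), CDH3 (−1.12 ± 0.28) and BMP5 (−0.62 ± 0.08), chosen after their values were seen, were lower. The changes of ALK and CDH3 were the largest in this list.

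Most other subunits of NuRD moved little. Of 15 measured, 6 were higher and 2 lower, with the largest rise for the paralog CHD5 (0.75 ± 0.15), a gene singled out after its value was seen, then MTA3 (0.54 ± 0.09), ZMYND8 (0.38 ± 0.06), CHD3 (0.35 ± 0.04) and RBBP7 (0.17 ± 0.03) (limma camera adjusted p = 0.897). Of 32 genes of G2 and mitosis, 12 were higher and 1 lower, 3 and 2 with 75th percentile scaling, with ASPM at 0.40 ± 0.05, CENPE at 0.32 ± 0.05, BUB1 at 0.23 ± 0.03 and CCNB2 at 0.16 ± 0.03 (adjusted p = 0.16). CCNB2 stood at −0.05 when all its probe sets were averaged. Of 31 genes of G1/S and replication, 7 were higher and 8 lower (7 and 9 when adjusted over the list alone; adjusted p = 0.294), and 1 and 13 with 75th percentile scaling. The transcription factor gene E2F1 rose 1.52-fold, whereas E2F8 fell 1.45-fold, UHRF1 1.18-fold and the cyclin gene CCNE1 1.17-fold. Of 19 cell death regulators, 5 were higher and 4 lower (adjusted p = 0.997). BMF rose 1.85-fold and BCL2L11 1.41-fold, both of which encode proteins that promote apoptosis, and BID fell 1.53-fold and BAD 1.44-fold, which promote it too. BCL2L11 stood at −0.04 when all its probe sets were averaged.

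Signalling and stress genes also split. Of 25 immediate early genes, 11 were higher and 4 lower (12 and 4 when adjusted over the list alone, limma camera adjusted p = 0.368). IER3 rose 2.69-fold. The naming rule also picked 3 of the list's feedback inhibitors of growth factor signalling, not all of them. These were SPRY4, up 2.53-fold, DUSP6, up 1.41-fold, and DUSP4, up 1.24-fold. Of 18 TGF-beta and YAP response genes, 3 were higher and 7 lower (adjusted p = 0.205): AMOTL2 fell 2.33-fold, CCN1 2.14-fold and LTBP1 1.46-fold, and the Hippo pathway kinase gene LATS2 rose 1.42-fold. Of 21 interferon response genes, 6 were higher and 2 lower (limma camera adjusted p = 0.863). IFI44 rose 3.09-fold, a fold that is not exact, since the gene was at the floor in 2 of the 12 arrays. IRF7 rose 1.80-fold and IFI44L, at the floor in all scrambled arrays with doxycycline, at least 6.07-fold, while IFIT5 fell 2.52-fold. Of 27 genes of the amino acid and endoplasmic reticulum stress responses, 6 were higher and 5 lower, and 4 and 9 with 75th percentile scaling (adjusted p = 0.795). The folate cycle gene MTHFD2 fell 1.83-fold and PHGDH, for serine synthesis, 1.72-fold, while HERPUD1 rose 1.24-fold and SESN2, also a p53 target, rose as given above. Of 24 glycolysis and hypoxia genes, 10 were higher and 6 lower (adjusted p = 0.897): the enolase gene ENO2 rose 2.57-fold, EGLN3 1.61-fold and BNIP3L 1.29-fold, and the collagen prolyl hydroxylase gene P4HA2 fell 3.64-fold. Of 17 cholesterol synthesis genes, 3 were higher and 4 lower, 1 and 7 with 75th percentile scaling (adjusted p = 0.41), with SQLE down 1.49-fold, NSDHL down 1.37-fold, STARD4 up 1.32-fold and MSMO1 up 1.11-fold.

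Single genes of other lineages changed by large factors, in both directions. Of 22 neuronal genes, 7 were higher and 2 lower (6 and 2 when adjusted over the list alone, limma camera adjusted p = 0.831). NEFH rose as above, the microtubule protein gene MAP2 2.29-fold and the synaptic scaffold gene DLG4 2.04-fold. RTN1 fell 1.15-fold, and SYT4, chosen after its value was seen, was also lower (−0.78 ± 0.15). Of 30 collagen and matrix genes, 11 were higher and 4 lower (12 and 4 when adjusted over the list alone, limma camera adjusted p = 0.831). COL1A2 stood 2.56-fold, LAMB1 1.21-fold and COL5A1 1.14-fold above scrambled arrays of the same times, and FBN2 1.43-fold below them. DCN (−1.34 ± 0.29) and COL12A1 (−1.08 ± 0.26), chosen after their values were seen, were also lower. Of 12 cancer-testis genes, 3 were higher and none lower (adjusted p = 0.759): SSX1 rose 7.11-fold, MAGEC1 3.27-fold and TEX14 1.86-fold. Of 10 markers of blood, epithelial and endothelial cells, CDH5 rose and the other 9 did not pass (adjusted p = 0.831). The median, the mean and the camera direction differed in sign for some lists. The PAX3-FOXO1 list had a median of 0.03, a mean of −0.04 and a camera direction of down. The sarcomere list had −0.07, 0.11 and down, the marker list of other cell types −0.03, 0.21 and down, the cell death list 0.05, 0.04 and down, and the myogenic regulators 0.00, 0.02 and down.

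**Figure D4:**
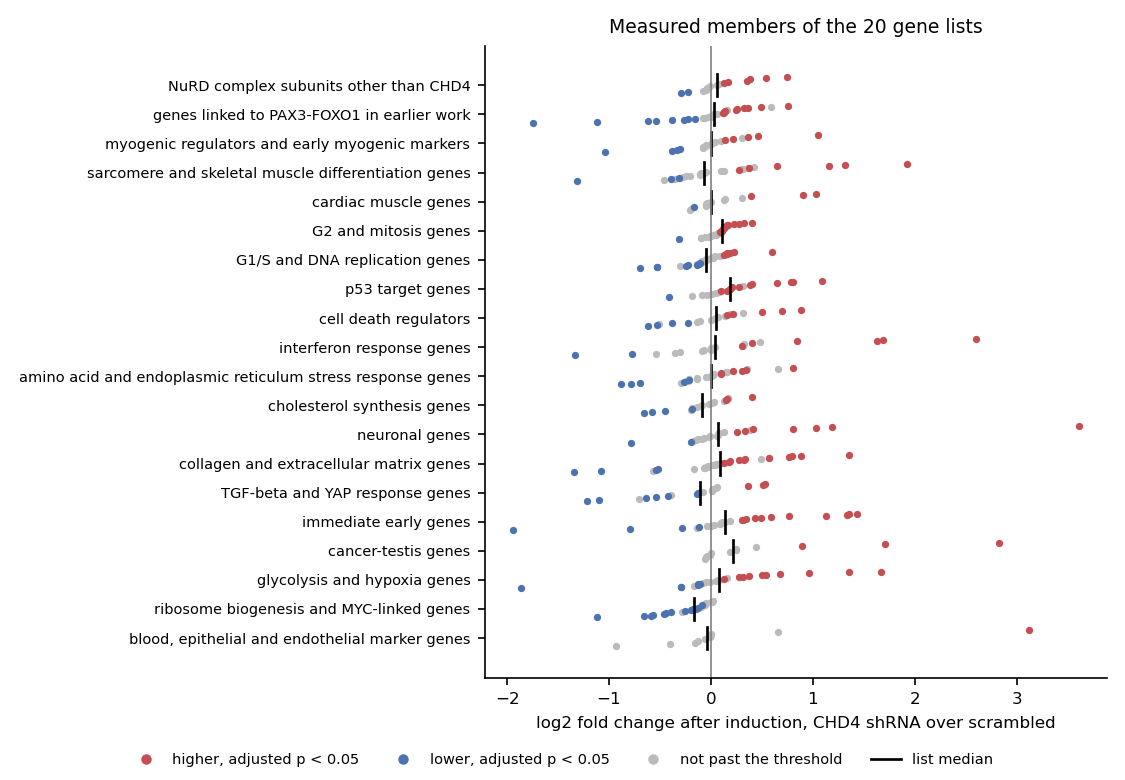
Log2 fold change after induction (horizontal axis) of each measured member of the 20 gene lists, with red points higher and blue points lower past the threshold of the limma test, grey points not past it, and a black bar at the list median. The ribosome biogenesis and MYC-linked list has 13 lower and no higher members, and the p53 target list 13 higher and 1 lower.

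The arrays at 0 h address whether the lines differed before the hairpins were switched on. The genes past the threshold there lay near the floor: SH3RF2 was at the floor in both scrambled arrays at 0 h and at least 1.94-fold higher in the CHD4 shRNA array (limma adjusted p = 0.000202), and so was the non-coding TLE1-DT, at least 2.10-fold (limma adjusted p = 0.00477). LOC105378419 (0.99), SLC23A3 (0.88) and HSD17B7P2 (0.78) had the next highest log2 fold changes. PDGFRB, for a growth factor receptor, and LILRB1, for an immune receptor, were at the floor in the CHD4 shRNA array and at least 1.36-fold and 1.23-fold lower (limma adjusted p = 0.0237 and 0.046). These were among 36 higher and 2 lower genes, and all 38 were at the floor in most of the other 11 arrays. None of the 20 lists passed limma camera at 0 h, with 0.459 as the lowest adjusted p. The single CHD4 shRNA array at 0 h was assumed to vary like the rest. The count was 14 with 75th percentile scaling, 0 with the stricter filter on dim genes, and 37 higher and 25 lower (62 genes) without scrambled replicate 1 at 0 h.

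To separate the effect of induction from this starting difference, the change after induction was set against the difference at 0 h. RGS4 rose by 6.39 ± 0.85 (log2, SE; limma adjusted p = 0.00572) beyond its difference at 0 h, SCN9A by 3.61 (at the floor in the CHD4 shRNA array at 0 h), PDZRN4 by 3.5, NEFH by 3.41 and HR, a nuclear receptor corepressor gene, by 3.39. MOBP (−2.69 or lower, at the floor in 2 of 3 CHD4 shRNA arrays), NCALD (−2.62), ISOC1 (−2.58 ± 0.14, limma adjusted p = 0.000576), C1QBP (−2.50) and RAB39B (−2.33) fell the most. SELENOP (4 ± 1.17, limma adjusted p = 0.0611), IFITM1 (2.92 ± 0.83, 0.0559), SSX3 (3.54 ± 1.01, 0.0558), KANK4 (−2.20 ± 0.93, 0.158), SLC35F2 (−2.00 ± 0.56, 0.0536) and MYC (−1.94 ± 0.59, 0.0663) did not pass. Their log2 fold changes stayed near those after induction, while the standard errors were larger. In all 1309 genes were higher and 989 lower, and 1035 and 1075 with 75th percentile scaling. The count was 1287 without the CHD4 shRNA array of 48 h and 3715 without that of 24 h. It was 1457 and 1474 without scrambled replicate 1 or 2 at 0 h, 1484 without replicate 2 at 48 h and 1490 without replicate 2 at 72 h.

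Single times were compared to see when genes changed. At 24 h RGS4 was already 21.9-fold higher (4.45 ± 0.33 SE, limma adjusted p = 0.00306), CDH5 7.52-fold, the non-coding LINC02724 5.26-fold and LINC00173, at the floor in both scrambled arrays at 24 h, at least 6.28-fold. ISOC1 was 5.63-fold, C1QBP 4.60-fold, the nicotinamide methyltransferase gene NNMT 3.79-fold and the nucleotide-binding protein gene HINT3, at the floor in the CHD4 shRNA array, at least 3.81-fold lower. RGS4 reached 85.1-fold at 48 h and 124-fold at 72 h (limma adjusted p = 0.000272). At 48 h SELENOP was 24.3-fold and IFITM1 15.3-fold higher, GUCY2D at least 15.1-fold, and MOBP, at the floor, at least 8-fold lower. By 72 h SELENOP was 31.4-fold, the sodium channel gene SCN1A 26.8-fold, IFITM1 23.4-fold and SSX3 21.0-fold higher. At that time KANK4 was 14.7-fold, NCALD 9.40-fold, the small heat shock protein gene HSPB3 9.03-fold, TRIM58 8.62-fold and the kinase gene NRK 8.14-fold lower. Genes past the threshold numbered 1728 higher and 825 lower at 24 h, 2815 and 1956 at 48 h, and 3188 and 2036 at 72 h (limma, 8 groups). With 75th percentile scaling these became 1078 and 998 at 24 h, 2220 and 2249 at 48 h, and 2407 and 2643 at 72 h, and after quantile normalization 1393 and 1077 at 24 h. At all 3 times 1220 genes were higher and 673 lower, where independent lists would share 63.4 and 13.4, and 87 genes had opposite calls at a pair of times. All spread in this fit came from the scrambled pairs, and the lone CHD4 shRNA array was assumed to vary like them. Some of the genes past the threshold at each time were at the floor in all scrambled arrays. The floor sets their spread near 0, so they pass easily. The 3 times also share the same spread for each gene and the same CHD4 shRNA line. Their lists are therefore not independent, and an overlap above that of independent lists does not by itself show a lasting effect. Without scrambled replicate 1 or 2 at 24 h the count at 24 h was 1530 or 1403. With array weights the counts were 207, 7816 and 2574 at 24, 48 and 72 h. The weights came from the fit with a common effect at these times. That fit takes a change over time as spread, so these counts cannot address a rise. Without scrambled replicate 1 or 2 at 72 h the count was 3776 or 3909 at 72 h, against 4035 at 48 h. The rise from 48 to 72 h was then not kept.

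Whether effects changed with time was tested directly, as the effect at 72 h minus that at 24 h. SCN1A (4.75), the non-coding A2M-AS1 (4.06), the proton-sensing receptor gene GPR4 (3.74), the plakin gene PPL (3.65) and the myelinating cell gene ERMN (3.38) had the highest log2 values and passed as moving up (limma). Their sizes and order are not exact, because floored values enter each: SCN1A was at the floor in all arrays at 24 h, A2M-AS1 and PPL in all 8 scrambled arrays, GPR4 in both scrambled arrays at 72 h and ERMN in the CHD4 shRNA array at 24 h. UGT3A1 (−3.26 ± 0.24), ANKRD6 (−3.19 ± 0.12), KANK4 (−3.10 ± 0.07), LINC02703 (−3.02) and PROM1 (−2.90), a stem cell surface marker, moved down the most. UGT3A1 also had the highest fold change in scrambled cells from 0 to 72 h, given below. In all 464 genes moved up and 523 down (limma), or 190 and 327 without genes at the floor in all scrambled or all induced CHD4 shRNA arrays, whose spread the floor sets near 0. The difference between RNA ends grew over the same times. Among the lists, cancer-testis genes moved up, with 3 of 12 members higher and none lower (5 when adjusted over the list alone; limma camera adjusted p = 0.000212; adjusted p = 0.228 with an estimated correlation). Of the 3, SSX1 lay above the floor in all arrays, while MAGEC2 and PAGE4 were at the floor in all scrambled arrays. Interferon response genes moved up, with 5 of 21 higher (5 higher and 1 lower when adjusted over the list alone; adjusted p = 0.0196; adjusted p = 0.228 with an estimated correlation). PAX3-FOXO1-linked genes moved down, with 4 of 31 lower (6 when adjusted over the list alone; adjusted p = 0.000741; adjusted p = 0.415 with an estimated correlation), and so did cholesterol synthesis genes, with 3 of 17 lower (5 when adjusted over the list alone; adjusted p = 0.00166; adjusted p = 0.228 with an estimated correlation). The balance turned without single arrays, to 367 up and 290 down or 361 and 279 without scrambled replicate 1 or 2 at 24 h (657 or 640 genes), and to 268 and 226 or 283 and 249 without replicate 1 or 2 at 72 h (494 or 532 genes). The balance was 160 up and 61 down with array weights (221 genes), which take a change of effect over time as spread. It was 159 and 371 with the stricter filter on dim genes (530 genes). More genes also moved up than down with the mean of probe sets (444 and 407) and with scrambled arrays of the same number paired (259 and 231). The same held without either scrambled array at 48 h (365 and 354).

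Scrambled cells were followed over time without the CHD4 hairpin. Doxycycline, the scrambled hairpin and time in culture were all present there and cannot be told apart. The actin-binding tropomyosin gene TPM4 fell 3.44-fold by 24 h and 5.52-fold by 72 h (−2.47 ± 0.09 SE, limma adjusted p = 0.00134). AP4S1, for an adaptor protein of vesicle coats, fell 2.62-fold, ARID3B, for a DNA-binding protein, 2.34-fold, and the centrin gene CETN2 2.10-fold by 24 h (limma adjusted p = 0.0232, 0.0342 and 0.015). The hair keratin-associated gene KRTAP4-4 lay between ARID3B and CETN2 at 24 h (−1.16). B3GALT5 (0.81), the sterol transporter gene ABCG1 (0.79), SH3D19 (0.75), NFIA-AS2 (0.74) and the lipid receptor gene S1PR1 (0.70) rose by 24 h. At 72 h the highest fold changes were those of UGT3A1 (12.7-fold, limma adjusted p = 0.00134), DNAJC5B (8.45-fold), the prostaglandin synthase gene PTGES (8.43-fold), the ubiquitin ligase gene RNF186 (at the floor at 0 h, at least 8.25-fold) and the citrullinating enzyme gene PADI2 (4.98-fold). After TPM4, the lowest were MYEOV (−2.01), TTC23L (−1.73), LINC01138 (−1.67) and ARID3B (−1.61). Past the threshold were 12 higher and 35 lower genes at 24 h, 574 and 432 at 48 h, and 848 and 690 at 72 h, each against 0 h with 2 arrays a side (limma). With 75th percentile scaling the split was 439 higher and 564 lower at 48 h and 655 and 750 at 72 h. The β-actin difference between RNA ends was 2.388 and 2.235 in the scrambled arrays at 0 h and 2.536 and 2.535 at 72 h. Single arrays moved these counts. At 24 h the count was 75 without scrambled replicate 1 at 0 h, 86 (61 higher, 25 lower) or 78 (56 higher, 22 lower) without replicate 1 or 2 at 24 h, 10 without either at 48 h and 1 without either at 72 h. The count at 48 h was 544 or 588 without replicate 1 or 2 at 0 h, 497 without either at 24 h, 207 or 399 without replicate 1 or 2 at 48 h and 413 without either at 72 h. At 72 h it was 779 without replicate 2 at 0 h, 909 without either at 24 h, 955 without either at 48 h, and 339 or 499 without replicate 1 or 2 at 72 h.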

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

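Except for the comparison with other choices of arrays and the limma comparison of 72 with 24 h, the tests in this part were chosen after results were seen, and some were reshaped after a first value. The comparison of early with later effects, and what would count for or against each explanation there, were also set after the genes had been seen. Intervals in this part come from resampling genes or probe sets that share the same arrays, so they leave out the spread between arrays.

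The size of the response, 6652 genes, was weighed against chance and against the RNA ends. In each of 27 possible ways, 1 array per induced time was called the silenced one. The real choice gave the most genes, and the highest other choice gave 1. Each other choice left at least 1 CHD4 shRNA array among the scrambled, which widens the spread, so its low count does not measure chance. The test also cannot tell the hairpin from another difference shared by the induced CHD4 shRNA arrays, such as the RNA ends. Loss of 5′ signal in the CHD4 shRNA arrays might lower many genes and, through the scaling of arrays, lift others. The highest lift of a 3′ control was 0.04 with a spread of 0.02, in β-actin. The 3′ signal of GAPDH stood at −0.07, −0.13 and −0.13 at 24, 48 and 72 h. By limma treat over all genes tested, 3304 genes were higher by more than 0.08. With 75th percentile scaling 3197 stayed higher, and the median over all genes moved from 0.033 to −0.036. A lift of the size seen in these control transcripts therefore does not account for most of the 4236 higher genes. How far other transcripts were lifted cannot be told from these controls. For the lower genes the question stays open: their 24 h effect was 0.38 of that at 72 h (0.36 to 0.41, 2036 genes; 0.44 when higher and lower genes were first pooled), and β-actin had reached 0.38 of its rise by 24 h.

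By 24 h 35 genes fell in scrambled cells, TPM4, AP4S1 and ARID3B among them, and these 3 stood higher with the CHD4 hairpin after induction (1.83, 1.71 and 1.25). From 0 to 72 h these 3 changed by −2.47, −1.23 and −1.61 in scrambled cells. In CHD4 shRNA cells they changed by −0.53, 0.4 and −0.16. The group is fragile: 25 or 22 genes fell, fewer than the 61 or 56 that rose, without scrambled replicate 1 or 2 at 24 h, 1 fell without either array at 72 h and 8 with the offset. Doxycycline or time acting on both lines alike would have lowered the CHD4 shRNA cells too. In the 29 genes above the floor in the CHD4 shRNA array at 0 h the scrambled median was −0.59 and the CHD4 shRNA median −0.003 (−0.25 to 0.07). This argues against such an action on the group only as far as 1 CHD4 shRNA array at each time can show, and 8 genes followed the scrambled fall. Chance highs in the scrambled arrays at 0 h would leave the CHD4 shRNA array lower at 0 h by about the scrambled fall, a median of −0.58 over all 35 genes. It differed by −0.09 (−0.21 to −0.02), which argues against chance highs for the group only as far as this 1 array can show. They stay open for 10 genes whose CHD4 shRNA value at 0 h was nearer to scrambled 24 h, 6 of them at the floor, and an effect of the scrambled hairpin itself was not tested.

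ISOC1, C1QBP and RAB39B had nearly their full fall by 24 h, as a direct action of the CHD4 hairpin on other RNAs could produce. Of 212 genes changed at least 2-fold whose 24 h effect was at least 0.8 of that at 72 h, 82 were lower, or 38.7%, against 25.8% of the 488 whose effect grew later (Fisher exact p over genes = 0.000843). The test takes genes as independent, though all share 1 CHD4 shRNA array at 24 h and 1 at 72 h. Its p leaves out the spread between arrays. Falls, unlike rises, are also bounded by the floor, which the test did not allow for. A higher share of lower genes would go with such a direct action and also with early loss of CHD4 itself. The hairpin sequence needed to tell them apart was not used here. A fault of single probe sets is unlikely for the 33 of these genes that could be checked, taken as a group. Their 45 other probe sets had a median of −0.76 (−1.02 to −0.57), with 41 below 0. C1QBP was among them (−2.58), while ISOC1 and RAB39B had no other probe set in this check. The median of the main probe sets was −1.23, and the interval reaches past −0.62, the stricter bound first set on the lowest genes alone.

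The effect of CHD4 silencing passed as different between 24 and 72 h in 987 genes (limma), which flagged the following results as a difference between times. Each time had 1 CHD4 shRNA array, and the spread came from scrambled pairs whose difference may be technical. Effects on genes raised after induction grew from 24 to 72 h by a log2 value of 2.5 for RGS4, 2.33 for CXCL8, 3.15 for SSX3 and 3.15 for SSX1. The values were 2.63 for IFITM1, 2.43 for TPTE2P2, 2.69 for GUCY2D, 2.29 for PDZRN4, 1.46 for RFX4 and 2.53 for IFI44L, none of an exact size, since both scrambled arrays at 24 or 72 h were at the floor. Effects on lowered genes deepened by −1.61 for NCALD, −1.68 or lower for MOBP (at the floor at 72 h), −3.1 for KANK4, −1.79 for SLC35F2, −0.54 for NSDHL and −1 for P4HA2. List members among raised genes changed by 0.72 for MYL1, 0.84 for RYR2 (at the floor in all scrambled arrays and with CHD4 shRNA at 24 h, so of unknown size), 0.39 for CDKN1A and 0.98 for IER3, while TP53INP1 and COL1A2 changed by −0.36 and −1.12. Among lowered genes the changes were 0.72 for IFIT5 and 0.39 for AMOTL2.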

How the results depend on the processing

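The tests were fixed before the data were examined, except those with the offset, without genes at the floor, and of scrambled cells at 24 and 48 h, which were chosen after seeing the data. CHD4 was lower under every alternative, from −1.234 with the mean of probe sets to −0.615 without the CHD4 shRNA array of 72 h (−0.669 without that of 24 h, the lowest without an array). Of 2126 values of named genes after induction under alternatives, 2091 kept direction and side of the threshold, 33 lost their call and 2 turned: with the mean of probe sets CCNB2 became −0.054 and BCL2L11 −0.041. With the genes named for other comparisons and the 2 lists that passed added, 3762 values stayed the same, 235 lost their call and 2 turned. After induction 6580 genes passed with quantile normalization, 6448 with the 75th percentile, 6228 without the filter, 6505 with the 50% filter, 6280 with the mean of probe sets, 7012 with a trend, 8567 with array weights, 6601 with induced arrays only, 7354 with 8 groups and 5962 without time. Signal over background limits what dim genes can show, as single CHD4 shRNA arrays do at every time. Where a value moved, the cause was not tested.

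The main counts, in the order after induction, 0 h, beyond 0 h, 24, 48, 72, 72 against 24 h, and scrambled 24, 48 and 72 h, were 6652, 38, 2298, 2553, 4771, 5224, 987, 47, 1006 and 1538. With a log2 fold change of at least 1 they were 700, 1, 520, 319, 849, 1118, 286, 6, 85 and 149. At 0 h the count was 14 with the 75th percentile, 104 without the filter, 0 with the 50% filter, 0 with a trend, 64 with array weights, 0 with the offset and 2 without floor genes. For 72 against 24 h it was 530 with the 50% filter, 221 with array weights, 422 with the offset and 517 without floor genes. For scrambled cells at 24 h it was 77 without the filter, 75 with a trend, 28 with array weights, 12 with the offset and 26 without floor genes. Array weights also gave 4633 beyond 0 h, 207 at 24 h, 7816 at 48 h and 2574 at 72 h, giving the CHD4 shRNA arrays of 24, 48 and 72 h weights of 0.22, 3.29 and 0.3. The weights were estimated with a common effect at these times, so an array lost weight where its effect differed from it.

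Of the lists, 2 passed after induction, 3 without the filter, 1 with the 50% filter, array weights or no floor genes, 0 with an estimated correlation and 13 with limma fry, which tests against no change and not against other genes. The adjusted p of the p53 targets was 0.0768 with the 50% filter, 0.125 with array weights, 0.0505 without floor genes and 0.457 with an estimated correlation, which also gave 0.457 for ribosome biogenesis. Nothing ties scrambled arrays of the same number together, and correlations between them after centring were −0.11 to 0.13; with the replicate block the counts were 6208 after induction, 25 at 0 h, 490 for 72 against 24 h, and 0, 357 and 813 in scrambled cells.

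Without each array in turn, where the effect could still be estimated, counts ran from 4743 to 6757 after induction, 29 to 62 at 0 h (62 without scrambled 0 h replicate 1), 1287 to 3715 beyond 0 h (without CHD4 shRNA 48 h and 24 h), 1403 to 2588 at 24 h (without scrambled 24 h replicate 2; 1530 without replicate 1), 3264 to 4776 at 48 h and 3776 to 5354 at 72 h. They ran from 494 to 987 for 72 against 24 h (lowest without scrambled 72 h replicate 1). In scrambled cells they ran from 1 (without either 72 h replicate) to 86 (without 24 h replicate 1) at 24 h, 207 (without 48 h replicate 1) to 1006 at 48 h and 339 (without 72 h replicate 1) to 1538 at 72 h. Lists ran from 1 (without CHD4 shRNA 24 h) to 2, and the adjusted p of the p53 targets from 0.00783 (without CHD4 shRNA 48 h) to 0.0779 (without 24 h).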

Other observations

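The test of neighbouring genes in this part was planned before its result was seen, while the list tests and the genes described first were chosen after results were seen. Over 72 h in doxycycline, scrambled cells gained expression of some muscle genes and lost that of some replication genes, while the β-actin difference between RNA ends went from 2.388 and 2.235 at 0 h to 2.536 and 2.535. Of 27 sarcomere and differentiation genes, 6 rose and none fell (7 when adjusted over the list alone), among them the troponin genes TNNI2 (1.05) and TNNI1 (0.89), the myosin genes MYH8 (0.95) and MYL1 (0.48), and CASQ2 (0.26) (limma camera adjusted p = 0.0197; adjusted p = 0.682 with an estimated correlation). Of 31 genes of G1/S and replication, 5 fell and none rose, with the same count adjusted over the list alone: the transcription factor gene E2F2 (−0.82), the sliding clamp gene PCNA (−0.32), POLE2 (−0.26), CHAF1A (−0.24) and PRIM1 (−0.18) (limma camera adjusted p = 0.000334; adjusted p = 0.286 with an estimated correlation). Genes of ribosome biogenesis and MYC-linked growth fell as well, 3 of 22 (6 when adjusted over the list alone; limma camera adjusted p = 0.0179; adjusted p = 0.682 with an estimated correlation). MYH8 and MYL1 rose over time without the CHD4 hairpin and stood higher with it, whereas TNNI2 was lower with it (−1.31 ± 0.29 SE, limma adjusted p = 0.0091), and the effects on TNNI2 and TNNI1 moved down from 24 to 72 h (−1.83 and −0.99, limma adjusted p = 0.0207 and 0.0146).

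Between 24 and 72 h of CHD4 silencing, the interferon genes IFIT1 (3.01, with floored values for CHD4 shRNA at 24 h and in all scrambled arrays, so of unknown size), IFI44L (2.53, at the floor in all scrambled arrays, so not exact), IFIT2 (1.18), IFIT5 (0.72) and RIGI (0.36) moved up in log2 effect. Among PAX3-FOXO1-linked genes, the receptor kinase gene ALK (−1.43, limma adjusted p = 0.00321), the microtubule gene DCX (−1.39), NHLH1 (−0.78) and ABAT (−0.23) moved down, and of the cholesterol genes NSDHL (−0.54), INSIG1 (−0.34) and HMGCS1 (−0.29) did. ALK was also lower over all induced times (−1.75 ± 0.22 SE, limma adjusted p = 0.000785). DCX, NHLH1 and ABAT did not pass over these times (0.13, 0.01 and 0.01). From 0 to 72 h in scrambled cells, ALK, DCX, NHLH1 and ABAT changed by −0.3, 1.21, −0.44 and −0.06. A downward move of DCX against scrambled arrays is therefore not shown to be a fall in the CHD4 shRNA cells. MYOD1, the master regulator of muscle fate, did not pass (−0.08, limma adjusted p = 0.11), and neither did MDM2, a p53 target (0.08, limma adjusted p = 0.177).

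Loss of a chromatin remodeller could raise stretches of neighbouring genes together. Among the genes raised at least 2-fold, 19 pairs were adjacent in the genome with gene families left out, MAP2 with UNC80 and CNTN1 with PDZRN4 among them. Random placement of the same number of genes gave 14.1 pairs on average and 22 at the upper bound of the random range (permutation p = 0.11, 1000 placements of 15592 ordered genes), so the test was negative. The genes lowered at least 2-fold formed 2 adjacent pairs against 2.5 (permutation p = 0.7).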
